A study of Mus musculus with 5 samples.

How the data were processed

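Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate KLF5, a zinc-finger transcription factor of the Krüppel-like family, on the mouse embryonic stem (ES) cell genome. KLF5 carried a V5 epitope tag, a short viral peptide recognised by an anti-V5 antibody. The labels give 5 libraries, each the only library of its group: anti-V5 and normal mouse IgG immunoprecipitates and input DNA from ES cells overexpressing V5-KLF5, and an anti-V5 immunoprecipitate and input DNA from untagged ES-D3 cells, an established mouse ES cell line. Per the labels, the V5-KLF5 cells came from C57BL/6 mice. Per the labels' protocols, cells were cross-linked with formaldehyde, chromatin was sheared by sonication, and Illumina libraries were made from the precipitated DNA.

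Deposited peak lists were used for the 3 immunoprecipitates. The input libraries enter only as the background against which the authors called peaks. Per the file headers, the lists were made with MACS2 2.1.0.20140616 on single libraries that were not pooled, each against the input of the same cells. Tags of 51 bp were extended to 250 bp without a fragment model, 1 tag per position was kept, the larger dataset was scaled to the smaller, the effective genome size was 1.87 Gb and the q-value cutoff was 0.05. The submitters' processing notes name the mm10 build and Bowtie 0.12.8, besides FastQC 0.10.1, deepTools 2.4.1, CASAVA, Partek and Cuffdiff, without the role of each. How reads that map to several places were treated is not given in the sources used here. For each peak the authors deposited a summit position, the pileup signal at the summit (the height of the extended tags), the −log10 p-value and −log10 q-value, and the fold enrichment, a ratio of (pileup + 1) to (input background + 1). These are the authors' values for each peak and served only to describe, rank or filter peaks within a list. The list of the untagged cells holds header lines and 0 peaks. Its run name gives another mouse ES line, JM8.N4, where the label gives ES-D3. The label was followed, and it is therefore uncertain which line this control is and whether it shares the background of the tagged cells.

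The input background (lambda, in the unit of the pileup) was recovered from the pileup and the fold enrichment. A Poisson test of pileup against it gave the deposited −log10 p within 1% for 99.98% of peaks, and 37.2% of peaks stood on the genome-wide background of 3.10. That background is the floor MACS2 applies, so an input coverage below it cannot be seen in the lists.

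Gene positions came from RefSeq genes of GRCm38.p6, the assembly that mm10 names, and coordinates are 1-based in that build. All 202 symbols of the gene lists matched. This gene table gives the start and end of each gene without strand, exons or transcripts. The planned distance to a transcription start site was therefore replaced by the distance of the summit to the nearer end of a gene, which holds start sites and 3′ ends alike. No genome sequence was used here, so the planned motif counts and the matching of genes on promoter CpG content were not run. Gene analyses used the 45366 V5-KLF5 peaks on assembled chromosomes and 21887 protein-coding genes.

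Location shares were set beside 100 draws of random positions on the same chromosomes, which include sequence that cannot be mapped. Intervals of shares are exact Clopper-Pearson intervals at 95%, and intervals of counts are exact Poisson intervals. They cover counting error only, because each group has 1 library, and no p-value here measures the spread between cultures. Before the data were examined, the tests, the alternatives except those named in the closing section, the rule for named genes and 15 gene lists were fixed: inner cell mass (ICM) and naive pluripotency, trophectoderm (TE) and trophoblast, primitive endoderm, formative and primed pluripotency, neural and ectoderm, mesoderm, differentiated tissue, fibroblast, 2-cell stage, housekeeping, KLF and SP family, epithelial junction, and FGF and MAPK, LIF and STAT3, and Hippo signalling. A gene counted as having a peak where a summit lay within 10 kb of either end. Each list's count was placed as a percentile among 10000 random lists of protein-coding genes of the same size, matched on the decile of gene density (gene ends within 100 kb). This matching, and gene ends in place of start sites, were chosen after the gene table was seen. Lists above the 97.5 or below the 2.5 percentile are described as standing apart. By chance at most about 0.75 of 15 lists would do so, and fewer where small lists have tied counts. The LIF and STAT3 list could not stand above even with 5 of 5 genes (95.5 percentile). The ICM and TE lists were compared by a two-sided Fisher's exact test and by a two-sided permutation test (100000 resamples) of the mean log2 fold enrichment of the strongest peak per gene. Genes are not replicates, so these tests describe the lists within 1 library. The strongest peak of a gene can rise with its number of summits, on which neither these tests nor the random lists were matched.

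The genes named were fixed by rule: the gene with the nearest end for the 10 peaks with the highest fold enrichment; in the ICM and TE lists, the 8 genes with the strongest peaks and every gene without a peak; in each other list, the 2 genes with the strongest peaks; Klf5 in every library; and every peak of a control library with 10 or fewer. Of the genes this rule names, 1 is not reported here. Other genes are named as chosen after their values were seen. Alternatives were stricter peaks (−log10 q of at least 5 or 10, fold enrichment of at least 5 or 10), merged peaks, other distances, overlaps and measures of strength, and other random lists. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. In tests on simulated data over 21887 genes, all 200 planted genes (100%) were found, and 4.0% of 500 random lists of 23 genes fell outside the 2.5 to 97.5 percentiles. The permutation test of 23 against 20 values called 5.4% of 1000 simulations without a difference and 88.5% of those with a difference of 1 SD. The ICM and TE difference found was smaller (0.47, against SDs of 0.82 and 0.76), so the 88.5% does not give the power at that size.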

Results

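V5 ChIP-seq was carried out in mouse ES cells overexpressing V5-tagged KLF5, with an IgG immunoprecipitate of the same cells and a V5 immunoprecipitate of untagged ES-D3 cells as controls. Sequencing depth was similar in the 3 immunoprecipitates. The V5 library of the V5-KLF5 cells had 28.8 M (mega) tags, of which 23.2 M remained after duplicates were removed. The IgG library had 31.9 M tags and 24.5 M remained, and the V5 library of the untagged cells had 28.2 M tags and 21.8 M remained. The input of the V5-KLF5 cells kept 30.2 M tags and that of the untagged cells 22.1 M. Each group was 1 library, so no difference between groups has a replicate check.

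The first comparison asks which peaks depend on the tagged protein. The V5 immunoprecipitate of the V5-KLF5 cells gave 45378 peaks, the IgG immunoprecipitate of the same cells gave 3, and the V5 immunoprecipitate of the untagged cells gave 0. The V5-KLF5 peaks covered 23.1 Mb, with a median length of 427 bp and a range of 250 to 4967 bp. Their median fold enrichment over input was 5.18, with quartiles of 4.15 and 7.45 and a maximum of 58.7. At a fold enrichment of at least 10 there were 5880 V5-KLF5 peaks and 0 in either control. The line of the untagged cells is uncertain because the file header and the label name different ones. Control signal under the V5-KLF5 peaks that stayed below the calling threshold was not analysed here.

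All 3 IgG peaks lay at the ribosomal RNA sequence of chromosome 17 (mm10), next to Rn18s-rs5, an 18S ribosomal RNA pseudogene at 39846354 to 39848202. They were at 39844020 to 39844664, 39845898 to 39846181 and 39848400 to 39848821, and the last lay inside the lncRNA AY036118 (39848112 to 39898385). Their fold enrichments were 1.66, 1.78 and 1.80 over an input background of 136 to 157, against a median background of 3.45 under the V5-KLF5 peaks. Each of the 3 lay entirely within a V5-KLF5 peak, where 1000 random placements on the chromosome gave a mean of 0.059 overlapping peaks and at most 2. These placements were independent of each other, whereas the 3 IgG peaks lay at the same locus. Both lists were also called against the same input. The 3 overlaps are therefore not separate observations, and the random maximum does not measure their rarity. The V5-KLF5 peaks there, at 39843067 to 39846544 and 39847860 to 39848893, had fold enrichments of 2.24 and 2.88.

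Klf5 itself (chromosome 14, 99298691 to 99313412) had 4 V5-KLF5 peaks in the gene or within 10 kb of it and 0 in both control lists. The strongest, at 99298213 to 99298911, had its summit 157 bp outside the left end of the gene and a fold enrichment of 10.6. Peaks inside the gene at 99298975 to 99299582 and 99301517 to 99301925 had fold enrichments of 3.92 and 4.73, and the peak beyond the right end, at 99320806 to 99321129, had 4.23. Those inside the gene had pileups of 30 and 40. With these fold enrichments, their input backgrounds lay above 6.13, the 95th percentile under V5-KLF5 peaks on assembled chromosomes. The input was thus already raised there, for a cause that was not tested.

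The strongest V5-KLF5 peak, with a fold enrichment of 58.7, lay on chromosome 9 at 44881239 to 44882844, 136 bp outside an end of Kmt2a, which encodes a histone H3 lysine methyltransferase. The next lay on chromosome 6 at 114968571 to 114970735, inside Vgll4, a cofactor of TEAD transcription factors, 957 bp from its end, with a fold enrichment of 54.9. The summit at Ctnna1, which encodes alpha-catenin, lay 191 bp outside that gene with a fold enrichment of 53.1, and the summit 592 bp from Mllt6 had 53.0. The summit 25 bp from Btbd8 had a fold enrichment of 49.1. The other top 10 summits lay farther from a gene end. Summits inside Tmem38b, the tyrosine kinase gene Src, Sipa1l3 and the transglutaminase gene Tgm1 stood 14374, 14232, 30240 and 4237 bp from the nearer end, with fold enrichments of 52.1, 47.4, 47.0 and 46.3. The summit 1683 bp outside Clpsl2 had 51.6.

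V5-KLF5 summits gathered at gene ends. Of the 45366 summits on assembled chromosomes, 12071 (26.6%, 95% interval 26.2 to 27.0) lay within 1 kb of an end of a protein-coding gene, 8.27 times the 3.22% of random positions (range over 100 draws 3.04 to 3.39), which include unmappable sequence. In the innermost 200 bp there were 6131 summits against a mean of 314 at random. A further 39.3% lay inside a protein-coding gene more than 1 kb from its ends, against 39.0% at random, which is within the range of the draws (38.4 to 39.8). Outside genes, 11.2% lay 1 to 10 kb from an end and 22.9% more than 10 kb away, against 8.62% and 49.2% at random. The gene table has no strand, so these ends are not resolved into start sites and 3′ ends.

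**Figure D1:**
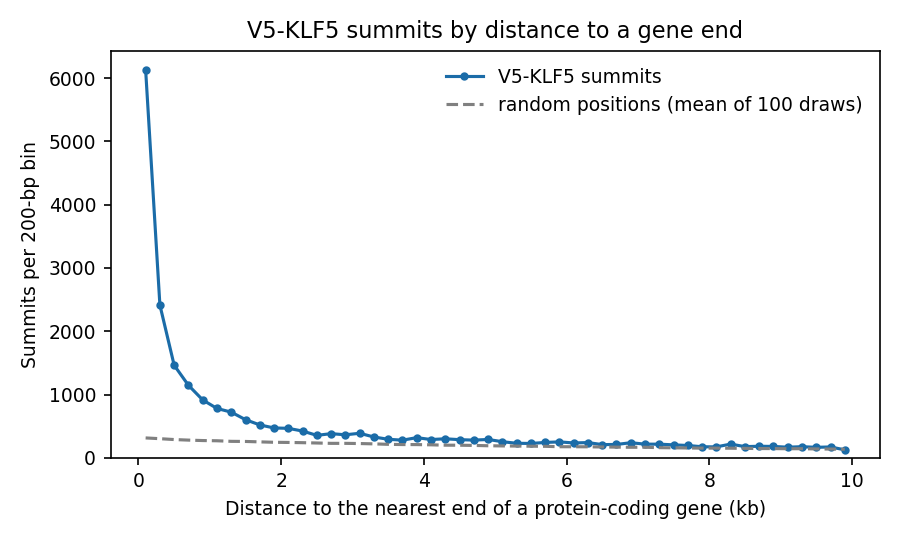
Number of V5-KLF5 summits per 200-bp bin (y axis) against the distance to the nearest end of a protein-coding gene in kb (x axis). The solid line with points is the V5-KLF5 library and the dashed line the mean of 100 draws of random positions. The innermost bin holds 6131 summits, against a mean of 314 at random.

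Peaks within 1 kb of a gene end had a median fold enrichment of 5.59 and the other peaks 5.12, a log2 difference of 0.12 (bootstrap interval over peaks 0.10 to 0.13). This order turned at the strong end of the list, where the difference among peaks with a fold enrichment of at least 10 was -0.082. The share of peaks within 1 kb of an end did not move one way with strength. It was 29.6% at a fold enrichment of at least 10 and 23.8% (interval 21.2 to 26.6) among the 1000 strongest peaks, against 26.6% of all peaks.

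The title of the series names an embryonic and an extra-embryonic fate, so genes of the ICM, which forms the embryo, and of the TE, which forms the placenta, were compared. All 23 genes of the ICM and naive pluripotency list had a V5-KLF5 summit within 10 kb of an end, above all 10000 random lists matched on gene density (random median 65.2%). Their median strongest peak, with a fold enrichment of 13.6, was also above all random lists. Of the 24 TE and trophoblast genes, 20 had a summit (83.3%, interval 62.6 to 95.3), which placed the list at the 96.2 percentile of its random lists, with a median strongest peak of 8.31 (89.7 percentile). The TE list stood above its random lists in 7 of 11 alternatives, among them summits within 1 kb (98.15 percentile) and within 50 kb (99.75 percentile). Among all protein-coding genes, 68.2% had a summit. The gap of 16.7 percentage points between the ICM and TE lists did not pass the test (Fisher's exact test, two-sided, p = 0.109). Its size depended on the window and on X-linked genes, with 3.08 points within 1 kb, 0 within 50 kb, where all genes of both lists had a summit, and 9.09 without X and Y genes.

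The 8 ICM genes with the strongest peaks were Fbxo15, Dppa5a, Pou5f1, Nanog, Tdgf1, Tfcp2l1, Nr5a2 and Sall4. Fbxo15, an F-box gene expressed in ES cells, had a summit 36 bp outside the gene on chromosome 18 with a fold enrichment of 32.3. Pou5f1, which encodes the pluripotency factor OCT4, had 7 summits, the strongest 1991 bp outside the gene on chromosome 17 (peak at 35503542 to 35506248) with a fold enrichment of 25.7. Nanog, a homeobox gene of naive pluripotency, had its strongest peak on chromosome 6 at 122702221 to 122703586, 4810 bp outside the gene, with 23.2. Tdgf1, the Nodal co-receptor gene, had a fold enrichment of 22.6 at a summit 1275 bp outside, and Tfcp2l1, Nr5a2 and Sall4, which encode transcription factors of ES cells, had 18.5, 18.5 and 17.9. The peak counted for Dppa5a, with 26.3, lay nearer to an end of Ooep. The weakest of the list was Klf4, with 4.29.

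The 8 TE genes with the strongest peaks were Tead4, Cldn4, Krt8, Elf3, Krt19, Dlx3, Eomes and Tfap2a. Tead4, which encodes a transcription factor required for TE formation, had a summit 266 bp inside its end on chromosome 6 (peak at 128299980 to 128301023) with a fold enrichment of 31.7. The tight-junction gene Cldn4 had 11 summits, the strongest 355 bp inside the gene with 17.4. Krt8 and Krt19, simple-epithelial keratin genes, had 16.8 and 13.4. The epithelial transcription factor gene Elf3 had 16.2 at a summit nearer to an end of Rnpep. Dlx3, Eomes and Tfap2a, which encode transcription factors of trophoblast, had 11.96, 11.6 and 11.3, and Tfap2a had 15 summits. Cdx2, a TE determinant named after its value was seen, had 8 summits, the strongest with 6.59. No summit lay within 10 kb of an end of Krt7, Esx1, Tspan8 or Plac1, though Tspan8 had 2 summits deeper inside the gene, and Esx1 and Plac1 are on chromosome X, where peaks were sparse.

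The strongest peak per gene had a mean log2 fold enrichment of 3.66 (SD 0.82 over 23 genes) in the ICM list and 3.19 (SD 0.76 over 20 genes) in the TE list. The difference of 0.47 (bootstrap interval over genes 0.01 to 0.94), a ratio of 1.38, did not pass the permutation test (two-sided p = 0.0614). Over these 2 tests the Benjamini-Hochberg adjusted p was 0.109 for both. The strength test depended on its settings: the permutation test passed in 5 of 10 alternatives and not in the other 5, with p-values from 0.00572 (pileup in place of fold enrichment, difference 0.68) to 0.416 (summits within 1 kb of gene ends, difference 0.23). Among the 5 that did not pass, a −log10 q of at least 5 changed no strongest peak and repeats the main result.

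**Figure D2:**
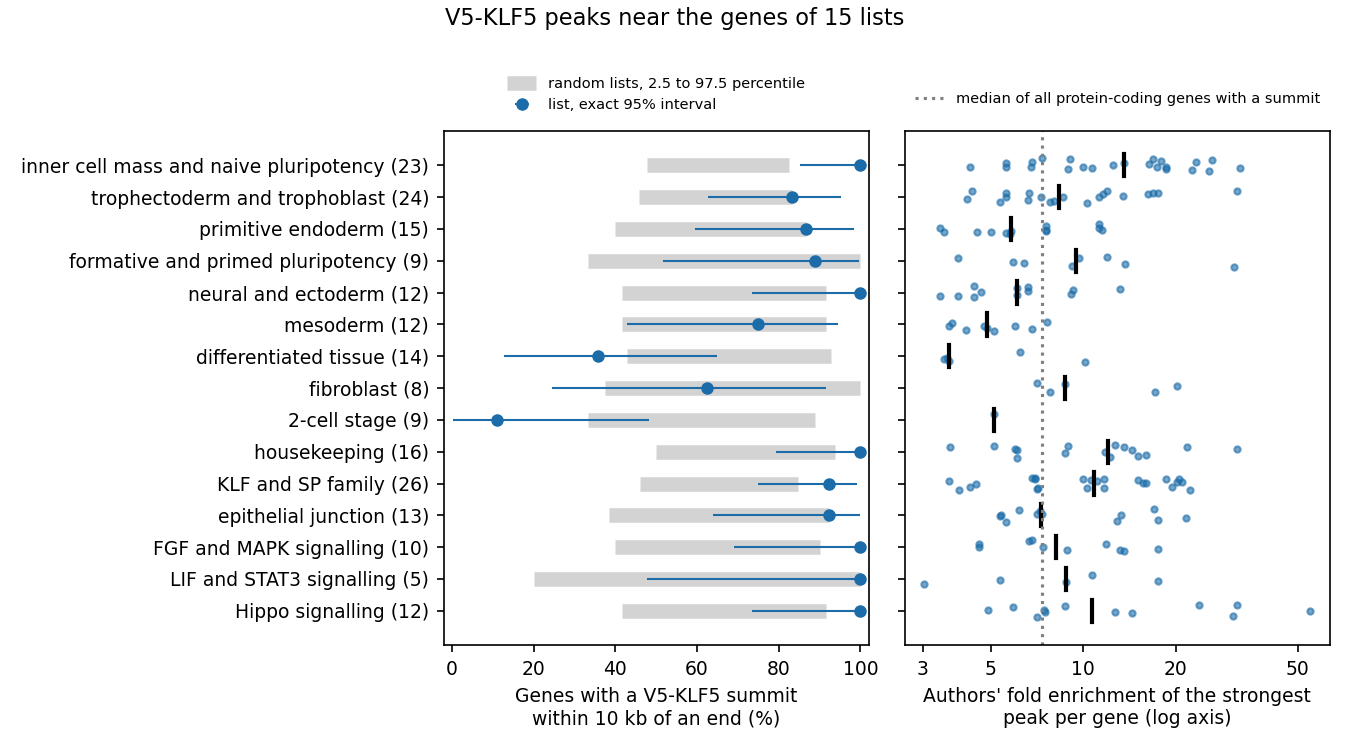
Left, the percentage of genes of each list (number of genes in brackets) with a V5-KLF5 summit within 10 kb of a gene end (points, with exact 95% intervals) beside the central 95% of random lists (grey bars). Right, the authors' fold enrichment of the strongest peak for each gene with a summit (points, log axis), the list median (black bars) and the median of all protein-coding genes with a summit, 7.32 (dotted line). The ICM list stands at 100% with a median of 13.6, and the differentiated tissue list at 35.7% with a median of 3.64.

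Genes of the Hippo pathway, which sets TE against ICM through TEAD factors, carried some of the strongest peaks. All 12 had a summit (99.6 percentile; 96.6 within 50 kb), led by Vgll4 at 54.9 and Tead4 at 31.7, and the list's median strongest peak of 10.7 stood at the 98.6 percentile of its random lists. Within 50 kb, 96.6 was the highest percentile the list could take, because all its genes had a summit. The KLF and SP family, KLF5's own, had a summit at 24 of 26 genes (99.9 percentile), led by Klf11 at 22.2 and Klf9 at 21.0, with a median of 10.8 (99.9 percentile). Klf6 and Klf8 had none within 10 kb of an end, though Klf8 had 4 deeper inside the gene. Signalling genes of the FGF and MAPK list had summits at 10 of 10 (99.2 percentile), led by the feedback inhibitor gene Spry4 at 17.5, at a peak nearer to Arhgap26, and by Fgf4 at 13.6. This list no longer stood apart in 3 of 11 alternatives. Among them, the setting within 50 kb could not place it above, because all its genes had a summit there (95.4 percentile). The LIF and STAT3 list, the pathway that maintains naive ES cells, had summits at 5 of 5 (95.5 percentile), led by Socs3 at 17.4 and Il6st at 10.7. The epithelial junction list had summits at 12 of 13 (97.4 percentile), led by Esrp1 at 21.7, whose peak lay nearer to Dpy19l4, and Cldn4 at 17.4. It stood apart in 5 of 11 alternatives.

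In the lists of other lineages, all 12 neural and ectoderm genes had a summit (99.7 percentile), but their median strongest peak was 6.10 (26.9 percentile), led by Sox1 at 13.2 and Pax6 at 9.27. That list no longer stood apart in 5 of 11 alternatives, a −log10 q of at least 10 among them. Mesoderm genes had summits at 9 of 12 (72.2 percentile) with a median of 4.87 (1.58 percentile), led by Tbx6 at 7.62, at a peak nearer to Ppp4c, and Mesp1 at 6.83. Primitive endoderm genes had summits at 13 of 15 (95.2 percentile) with a median of 5.82 (16.9 percentile), led by the laminin genes Lamb1 at 11.5 and Lama1 at 11.2. With summits inside genes counted, that list stood at the 97.8 percentile, the only 1 of 11 alternatives in which it stood above. Its lowest was the 60.35 percentile, within 1 kb. Formative and primed pluripotency genes had summits at 8 of 9 (91.0 percentile) with a median of 9.44 (93.8 percentile), led by the DNA methyltransferase gene Dnmt3a at 31.0 and Pou3f1 at 13.7.

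Genes of differentiated tissues had summits at 5 of 14 (0.565 percentile), led by Sftpc at 10.1, at a peak nearer to Lgi3, and Ptprc at 6.21, and their median of 3.64 stood at the 0.060 percentile. The list no longer stood apart within 50 kb (19.3 percentile) or at a fold enrichment of at least 10 (11.1 percentile). Of the 2-cell stage list, 1 of 9 genes had a summit (0.080 percentile), Zfp352 at 5.12. At a fold enrichment of at least 10 no gene of the list had a summit. The 10.9 percentile was then the lowest it could take, so it could not stand below. Several of its other genes, such as Zscan4c, Zscan4d and Zscan4f, have near-identical copies, so the lack of a called peak there is uncertain. The fibroblast list had summits at 5 of 8 (35.5 percentile), led by Vim at 20.1 and Col1a1 at 17.2. Housekeeping genes had summits at 16 of 16 (99.8 percentile) with a median of 11.996 (99.8 percentile), led by Ppia at 31.7. In all, 6 of 15 lists stood above and 2 below the range of random lists.

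Peak density differed between chromosomes. It ran from 12.4 per Mb on chromosome 14 to 29.3 on chromosome 11 among the autosomes, with a median of 18.5. Chromosome X had 600 peaks, 3.52 per Mb (interval 3.24 to 3.81), which is 0.190 of the autosomal median, and 32.3% of its protein-coding genes had a summit within 10 kb, against 59.0% to 79.4% on the autosomes. Its density ratio fell to 0.115 among peaks with a fold enrichment of at least 10. The median pileup of X peaks was 20, against 23 to 25 on the autosomes, and 10.0% of them stood above the genome-wide input background, against 59.4% to 68.3%. Their median fold enrichment was 5.12, against 5.12 to 5.37 on the autosomes. The other X peaks stood on the background floor. A lower input cannot be seen there and would leave their fold enrichment understated, so the cut on fold enrichment may remove more peaks on X. Chromosome Y had 6 peaks, with a median pileup of 81.5 and a median fold enrichment of 1.86. Their mean input background was 8.43 when peaks with a background of 20 or more were left out, so it understates the background of the 6.

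**Figure D3:**
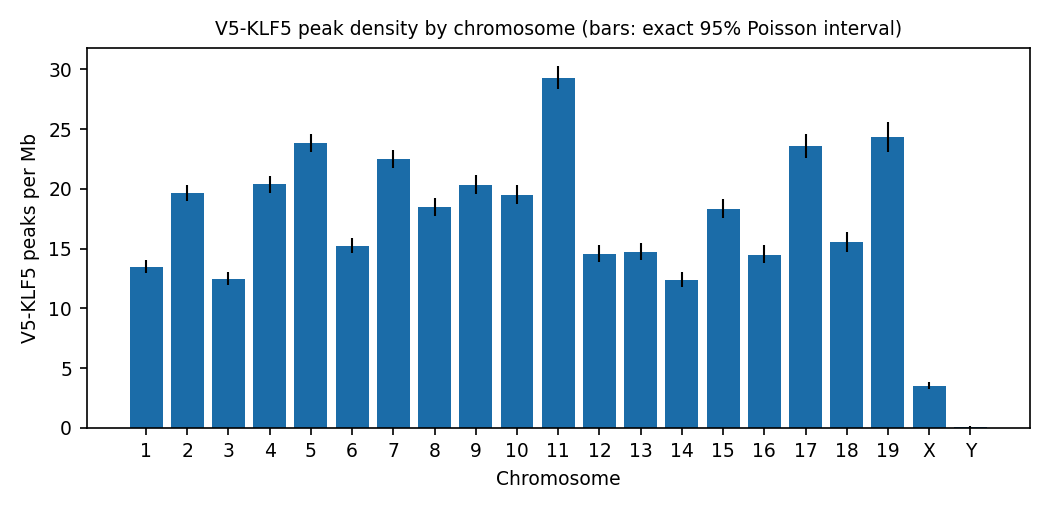
V5-KLF5 peaks per Mb (y axis) for each chromosome (x axis), counted over the span from the first to the last annotated gene or peak, with exact 95% Poisson intervals. Autosomes range from 12.4 to 29.3 per Mb and chromosome X has 3.52.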

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

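The test of the scaffold JH584304 was chosen only after its values were seen. The V5-KLF5 list held 12 peaks on scaffolds outside the assembled chromosomes, which the comparisons of genes did not use, and neither control list held any there. They drew attention as a signal outside the comparisons that lay above the control level. The control lists held only 3 and 0 peaks in all, so the lack of control peaks says nothing particular about scaffolds. Of these, 7 lay on GL456216 (assigned to chromosome 4), with fold enrichments of up to 11.5. Repeated sequence collapsed in the assembly was weighed as a technical explanation. It would raise the input background. The median background of the 12 peaks was 3.18 (bootstrap interval 3.10 to 4.50), below the 95th percentile on assembled chromosomes (6.13), which argues against it for the set as a whole. The exception is JH584304, which is assigned to no chromosome and whose 2 peaks stood on backgrounds of 40.0 and 85.1 with fold enrichments of 3.12 and 2.87, in line with collapsed repeats there. No biological explanation was tested.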

How the results depend on the processing

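The alternatives that count summits inside genes, leave out X and Y genes, or draw random lists by gene length or without receptor genes were chosen only after the data were seen. The V5-KLF5 list shrank from 45378 peaks to 21705 at a −log10 q of at least 10, 24396 at a fold enrichment of at least 5 and 5880 at 10, while the 3 IgG peaks became 0 under each of these, so their overlap could not be recomputed there. Under the other overlap rules it stayed at 3 of 3. The share of summits near a gene end, 26.6% within 1 kb, was 20.5% within 500 bp, 44.6% within 5 kb and 32.2% with the ends of all annotated genes. With stricter peaks it was 27.5% and 29.9% (−log10 q of at least 5 and 10) and 29.2% and 29.6% (fold enrichment of at least 5 and 10), each outside the counting interval. The excess strength of peaks near gene ends, 0.12 on the log2 scale, shrank to 0.021 at a −log10 q of at least 10, with an interval reaching 0, and reversed to -0.082 at a fold enrichment of at least 10. The cause was not tested. The density ratio of X to the median autosome, 0.190, was 0.152 at a −log10 q of at least 10 and 0.115 at a fold enrichment of at least 10. The ICM minus TE strength difference of 0.47 passed the permutation threshold at 0.49 within 50 kb, 0.91 with −log10 q and 0.68 with pileup as the measure, 0.58 with summits inside genes and 0.50 without X and Y genes, and did not in the other 5. It had the same sign in all 10 alternatives. The ICM minus TE gap of 16.7 percentage points ranged from 0 within 50 kb, where both lists reach 100% and no difference could appear, and 3.08 within 1 kb to 23.4 at a fold enrichment of at least 10, and passed Fisher's exact test in 0 of 8 alternatives. In both ICM and TE tests, a −log10 q of at least 5 left the values of the lists unchanged, so it repeats the main result. Between 5 and 8 lists stood above the random range, and the ICM, housekeeping and KLF and SP lists did so in all 11 alternatives. The TE list did so in 7 of 11, the epithelial junction list in 5 and the primitive endoderm list in 1. The Hippo list stood above in 10 of 11, the FGF and MAPK list in 8 and the neural list in 6, with a lowest percentile of 27.1. The 2-cell list stood below in 10 of 11 and the differentiated tissue list in 9. Within 50 kb the Hippo and the FGF and MAPK lists could not stand above, since all their genes had a summit. At a fold enrichment of at least 10 the 2-cell list could not stand below, since none of its genes had a summit. Lists below the range numbered 1 within 50 kb and 0 at a fold enrichment of at least 10. The planned motif counts, start-site distances and CpG matching were not run, for want of sequence and strand. No paired analysis was possible because each group is 1 library. Weak sites may be missed: the lowest listed pileup was 11, against a background of 3.10. The effect of depth was not tested.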

Other observations

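The tests of the input background on X and of the IgG peaks, the criterion by which the halving test on X was questioned, and the tests of gene families, noncoding genes and the ICM list against lists other than TE were chosen only after the results were seen. Gene families parted sharply by V5-KLF5 peaks. All 39 Hox genes, the homeobox clusters of the body axis, had a summit within 10 kb of an end, against a random median of 71.8%, though with a median strongest peak of 6.68. Within 1 kb, 22 of them had a summit (56.4%), near the 50.5% of all protein-coding genes. Genes in clusters can share summits, so the 39 are not separate observations. Ribosomal protein genes had summits at 75 of 80 and genes of histone methylation and Polycomb (Kmt, Kdm, Ezh, Pcgf and Cbx symbols) at 38 of 41, with 35 of these within 1 kb of an end. Olfactory receptor genes had summits at 50 of 1110 and vomeronasal receptor genes at 14 of 353, where random lists matched on gene density had medians of 70.4% and 68.8%. Beta-defensin genes had 6 of 42 and keratin genes 19 of 53. The random lists were not matched on mappability, and the treatment of reads that map to several places is not known. The lack of called peaks at receptor and beta-defensin genes is therefore uncertain where copies are alike. Proteasome subunit genes had 34 of 39, solute carrier genes 298 of 375 and Zfp zinc-finger genes 286 of 397, the last within the range of random lists.

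Among noncoding genes, the Mir290a, Mir291a and Mir295 genes of the ES-cell microRNA cluster on chromosome 7 had 8 summits each within 10 kb, with a common strongest summit at a fold enrichment of 14.3. Mir302a, Mir302b and Mir367 had 2 each, with a common strongest of 6.21, while Mir17 and Mir92-1 had 0. The neural Mir124a-1 had 6 summits and the strongest peak of the 19 microRNA genes looked at, 16.96, and Mir9-1 had 10.8 and Mir200a, Mir200b and Mir429 10.7. Of 408 tRNA genes, 143 (35.05%, interval 30.4 to 39.9) had a summit within 1 kb, against 14.7% of 1228 miRNA genes and 50.5% of protein-coding genes. These shares are not like for like, because the windows at the ends of a longer gene cover more sequence. No random share was computed for these classes. The densest 100-kb bin, on chromosome 10 from 81400000 to 81499999 with Nfic, Celf5, Ncln and S1pr4, held 29 summits, with no random expectation computed. The genes with the most summits within 10 kb were Midn and Septin1 with 16 each, then the ephrin receptor gene Epha2 and Tfap2a with 15 each.

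The strongest peak per gene separated the ICM list from some lists but not from others. Over 7 permutation tests with Benjamini-Hochberg adjustment, the strongest peaks of ICM genes exceeded those of neural and ectoderm genes by 1.08 on the log2 scale (adjusted p = 0.0021) and of primitive endoderm genes by 0.98 (adjusted p = 0.00238). By the same permutation test, the differences from the TE list (0.47, adjusted p = 0.143), housekeeping (0.28, adjusted p = 0.346), KLF and SP (0.33, adjusted p = 0.233), epithelial junction (0.45, adjusted p = 0.217) and Hippo genes (-0.037, adjusted p = 0.909) did not pass. Genes in both lists were left out. The KLF and SP comparison therefore used 21 ICM genes, without Klf2 and Klf4, against 22, where the others used all 23 ICM genes. In the primitive endoderm list, Col4a1 and Col4a2 shared their strongest summit (fold enrichment 7.57), so the same peak entered that test under both genes. Genes are not replicates, and these tests describe 1 library. They were not matched on the number of summits, from which the strongest peak is taken. The median was 4 summits per gene in the ICM list, 2.5 in the neural and 2 in the primitive endoderm list. In the lists that did not pass it was 3 to 4. The differences may therefore reflect more summits per gene as well as stronger ones.

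Fewer genes on X would leave its peaks per protein-coding gene within the autosomal range, but X had 0.621 against 1.61 to 2.85. This argues against fewer genes as the whole cause of the sparse X peaks. A constant loss of mapped sequence that removed whole peaks would thin weak and strong peaks alike. The median pileup of X peaks was 20 (bootstrap interval 20 to 21) against 23 to 25, which argues against such a loss as the whole cause. A loss of mapped positions within peaks would lower the pileup itself, so the test cannot speak to it. A single copy of X may contribute: X peaks with a pileup of at least 25 numbered 0.2008 per gene (interval 0.174 to 0.231), just inside the 0.198 to 0.369 of autosomal peaks with a pileup of at least 50 and below their median of 0.248, and 10.0% of X peaks stood above the genome-wide input background against 59.4% to 68.3%, as a lower mappability would also give. Another test came out against a single copy as the whole cause. Halving every autosomal pileup left 0.933 to 1.63 peaks per gene, and the 0.621 of X lay below that range. This had been set beforehand as the outcome that would speak against a single copy. That bound was questioned only after the result was seen, because it rests on simulated halving and 56.5% of the halved peaks fell under a pileup of 18, the lower quartile of the list. The 20.7% of listed peaks under that pileup follows from its being the quartile and does not show that the list is thin there. The outcome against a single copy as the whole cause was therefore kept. A further cause on top of a single copy would give the same outcome, so the test cannot exclude a single copy as a part. A single copy therefore remains a hypothesis, with mixed evidence as the whole cause and not excluded as a part of it. Fewer binding sites on X stay open and untested.

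The 3 IgG peaks inside V5-KLF5 peaks at the ribosomal RNA sequence may reflect collapsed repeats. Their lowest input background, 136, lay far above the 99th percentile under V5-KLF5 peaks, 7.67. No biological explanation was tested.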
